A study of Mus musculus with 8 samples.

How the data were processed

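The series holds RNA-seq of the corpus callosum of PLP-150Q mice in 8 libraries. Poly(A) RNA was extracted from the frozen tissue, per the labels' protocols. The groups were taken from the sample titles, which number the libraries 1 to 4 as control and 5 to 8 as LAQ. No label gives a sex, litter, cage, dissection date or sequencing batch. The numbers are not shared between the groups, so no library of one group was matched to one of the other.

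Raw read counts per gene symbol were deposited by the authors in one table, and they were whole numbers with a different total in each library. A second deposited table holds normalized signal, which is the raw count divided by 1 size factor per library. The ratio of the 2 tables was the same for every gene of a library, with a largest relative deviation of 5.1e-15. Those factors equalled the median of ratios of the raw counts. The submitters' processing notes list bcl2fastq 2.17.1.14, STAR 2.5.2b, HTSeq and DESeq2 1.10.1, and the genome build GRCm38.p3. The gene annotation release, the strand setting and any read filter were not given in the sources used here. Reads that fit several near-identical genes, or overlapping genes on opposite strands, may therefore have been divided or dropped, and such genes are named as uncertain. Both tables hold 1 column per library, and 0 columns were left unused.

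The raw table lists 41128 genes, of which 25164 had a count in at least 1 library. Total counts ranged from 8790749 to 12021429 per library. Genes were kept by edgeR's filterByExpr with its defaults (minimum count 10, minimum total count 15), which left 15771. Library sizes were scaled by TMM, and LAQ was compared with control by edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with robust estimation off. The test was two-sided, all 8 libraries entered the fit, and no covariate was used. The p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The standard error of a log2 fold change was computed as its size divided by the square root of the F statistic. Values per library are CPM, counts scaled to a common library size with the TMM factors, and log2 values used a prior count of 2.

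Gene lists for cell types, brain regions and pathways were fixed before the data were examined. Of 549 distinct symbols, 545 were found as written and 2 under an older symbol, 2 were not found, and 43 were found but lay below the expression filter. The lists, without the sex-linked genes, made 38 tests with camera at its preset correlation of 0.01, adjusted over the lists. The lists were also tested with an estimated correlation, with fry (directional and mixed), and with an exact two-sided permutation of the mean z score over all 70 assignments of the libraries. The smallest p which that permutation can give is 0.0286.

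The named genes also followed a rule fixed at that time. It took up to 10 genes per direction past the threshold with a mean log2 CPM of at least 1, no overlap between the groups and a symbol that is not a predicted or clone name. Where fewer than 5 qualified in a direction, genes of smallest p with the same expression and kind of symbol were added up to 5. It further took a panel of 8 genes, among them Prkg2, Myrf, Mbp, Htt, Ahr, Cyp1b1 and Ppargc1a, and up to 4 members of smallest p from each list discussed. The panel and the list of cGMP signalling genes were written with the study's interest in Prkg2 in mind.

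The alternatives covered normalization (median of ratios, library size alone, the deposited factors), filters (none, or at least 1 CPM in 4 libraries), tests (DESeq2 1.42.0, voom with and without sample weights, robust edgeR), covariates (1 surrogate variable from sva 3.50.0, or the cortical neuron score), a threshold of 0.1, and leaving out each library in turn. A fit without the LAQ libraries 5 and 7 was added after the data had been seen. The myelin, septal, striatal, hippocampal and thalamic scores were also used as covariates, 1 at a time, in edgeR. Transcript length, GC content and gene positions came from GENCODE M21 on GRCm38, which gave a length and GC content for 95.0% of the tested genes. The steps were tested on simulated counts for LAQ against control on the same 15771 genes, with 50 genes changed at each of 4 sizes. The test recovered 40% of the genes at 1.5-fold, 80% at 2-fold, 98% at 3-fold and 94% at 4-fold, with 5 false calls among 161. In the simulated lists, whose genes varied independently, camera called the list shifted by 0.4 on the log2 scale and 2 of the other lists. That run therefore does not show how camera behaves on lists whose members vary together. The genes of the first simulation also varied independently, so its recovery rates may not hold where many genes differ together between libraries. Figures were drawn with matplotlib 3.10.9.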

Results

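RNA was sequenced from the corpus callosum of PLP-150Q mice, a Huntington's disease model in which a mutant huntingtin fragment is expressed in oligodendrocytes. The mice were 3 months old when treatment began and received LAQ at 5 mg/kg, or purified water, for 2 months. LAQ was read as laquinimod, an oral immunomodulator studied in multiple sclerosis and Huntington's disease. There were 4 control libraries (replicates 1 to 4) and 4 LAQ libraries (replicates 5 to 8). The labels do not say that each came from a separate mouse, and if some did not, the p-values measure only the spread between these samples, which may be technical. The control libraries held 8790749 to 11972197 counted reads and the LAQ libraries 9634156 to 12021429. No 2 libraries of a group differed by less than sampling noise, with a chi-square per degree of freedom of 4.24 to 6.07 between control libraries. It was 7.87 to 8.93 between LAQ 5, 6 and 8, and 16.1 to 25.6 between LAQ 7 and those 3. Between 20392 and 21214 genes had a count in a library. Xist, the RNA of the inactive X chromosome, stood at 51.5 to 86.7 CPM in all 8 libraries. Mitochondrially encoded genes took 1.42% to 1.91% of the counts. The comparison asked how LAQ alters gene expression in the dissected white matter of this model. Neuronal RNA was present in the pieces too. In control the mean log2 CPM was 8.19 for the synaptic transmission list and 7.03 for the cortical excitatory list, beside 7.30 for the myelin list.

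The genes with the smallest p-values, 5 in each direction, were taken from those with a mean log2 CPM of at least 1 and an established symbol. Dgat2, which encodes the enzyme of the last step of triglyceride synthesis, averaged 98.0 ± 5.65 CPM in control (SD, n = 4) and 135 ± 12.96 CPM in LAQ (SD, n = 4), a 1.38-fold difference. Actb (beta-actin) averaged 577 ± 59.5 CPM in control and 787 ± 56.9 CPM in LAQ (SD, n = 4 each). Gbp4, an interferon-inducible GTPase, stood at 2.87 ± 0.75 and 7.59 ± 2.39 CPM, and Fst (follistatin, an activin antagonist) at 2.78 ± 0.37 and 5.77 ± 1.32 CPM. Tbc1d15, a regulator of Rab GTPases, stood at 47.6 ± 3.13 and 62.0 ± 2.71 CPM. On the lower side, the long noncoding RNA Miat averaged 127 ± 15.1 CPM in control and 83.7 ± 5.20 CPM in LAQ, and the transcription factor Arnt2 averaged 257 ± 23.2 and 179 ± 11.4 CPM. Yam1 (577 ± 60.9 against 392 ± 39.3 CPM), Scube1 (36.7 ± 2.11 against 23.4 ± 3.54 CPM) and the transcription factor Sox5 (37.3 ± 4.28 against 24.1 ± 2.43 CPM) completed these 10 genes. In each of the 10, the 4 LAQ libraries lay outside the range of the 4 control libraries. Their log2 fold changes were 0.47 for Dgat2, 0.45 for Actb, 0.38 for Tbc1d15, 1.38 for Gbp4, 1.06 for Fst, -0.60 for Miat, -0.52 for Arnt2, -0.56 for Yam1, -0.65 for Scube1 and -0.63 for Sox5. Gbp4 has close paralogs, so its count is uncertain.

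None of the 10 passed the main test. By edgeR's quasi-likelihood test, 0 of 15771 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.136, while 1750 genes (752 higher and 998 lower in LAQ) had an unadjusted p under 0.05 where 788.55 were expected by chance. DESeq2, with its own size factors and filter (15403 genes adjusted), called 129 genes on the same counts, 27 higher and 102 lower, and all 10 genes above were among them. Without LAQ 7, 339 genes passed edgeR's test (117 higher and 222 lower), again with all 10 genes, and 3132 had an unadjusted p under 0.05, whereas leaving out any one of the other 7 libraries gave 0 genes past the threshold. With all 8 libraries, edgeR called 25 genes without an expression filter and 25 with 1 surrogate variable. With the cortical neuron score as a covariate 757 genes passed, 334 higher and 423 lower. That score was lowest in LAQ 7, and 319 of the 339 genes called without LAQ 7 were among the 757. With the other regional scores the counts were 368 (myelin), 52 (septal), 24 (striatal), 0 (hippocampal) and 0 (thalamic and habenular), and the last 2 left 1245 and 1088 genes at an unadjusted edgeR p under 0.05. Across the tested genes, 438 were higher and 569 lower without overlap between the groups, 6.39% in all against 2.86% by chance. The surplus of lower genes at an unadjusted edgeR p under 0.05 was not stable. A loess correction gave 733 higher and 747 lower for GC content, and 897 higher and 796 lower for transcript length.

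In GRCm38 with the GENCODE M21 annotation, Dgat2 lies on chromosome 7 from 99153658 to 99182719, Actb on chromosome 5 from 142903115 to 142906754 and Tbc1d15 on chromosome 10 from 115197872 to 115251467. Gbp4 lies on chromosome 5 from 105115767 to 105139586 and Fst on chromosome 13 from 114452290 to 114458951. Miat lies on chromosome 5 from 112213228 to 112229395, Arnt2 on chromosome 7 from 84246278 to 84410176, Scube1 on chromosome 15 from 83604999 to 83725021 and Sox5 on chromosome 6 from 143828425 to 144781977. Yam1 was not matched to that annotation. Prkg2 lies on chromosome 5 from 98929773 to 99037351 and Cyp1b1 on chromosome 17 from 79701537 to 79715061. Miat is annotated as a long intergenic noncoding RNA and the other matched genes as protein-coding.

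**Figure D1:**
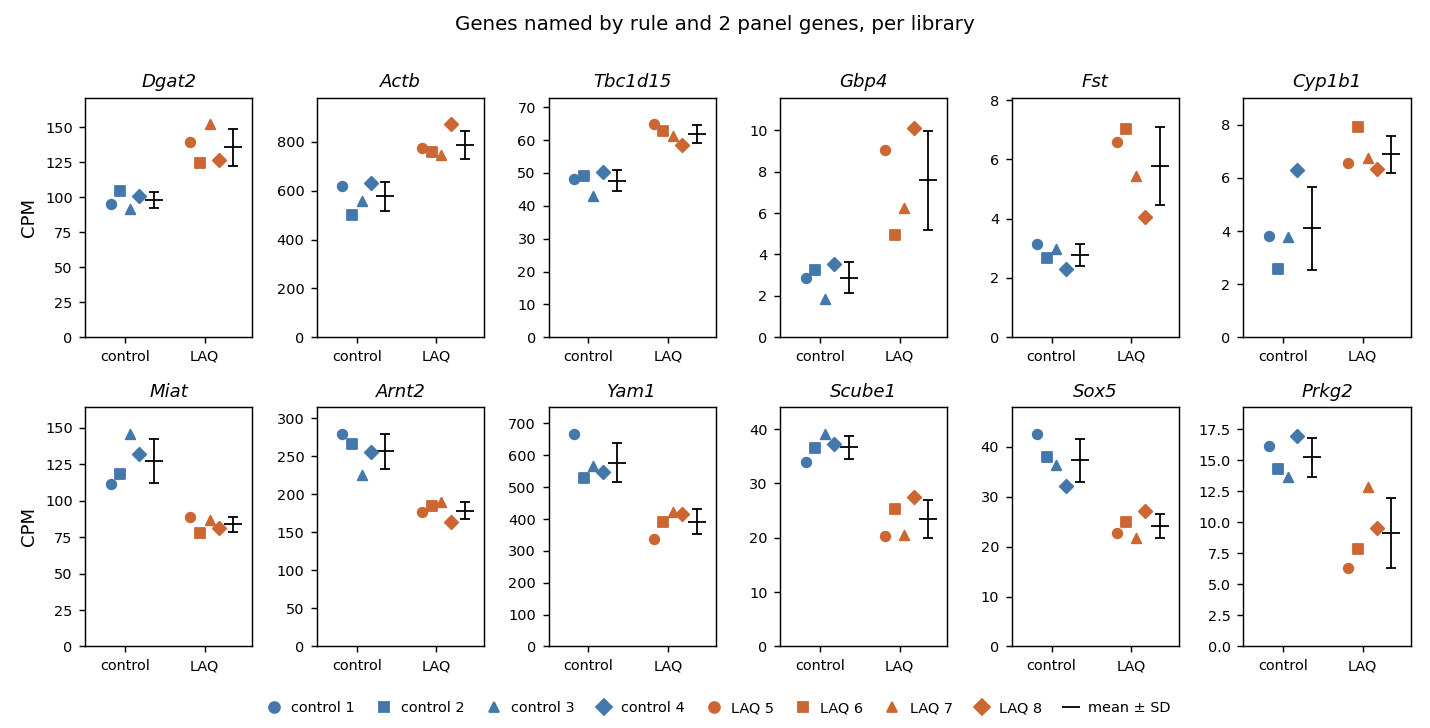
CPM (linear axes from 0) of 12 genes in each of the 8 libraries, with control libraries in blue, LAQ libraries in orange and the mean ± SD of each group in black. The 4 LAQ libraries lie above all control libraries for Dgat2, Actb, Tbc1d15, Gbp4, Fst and Cyp1b1, and below them for Miat, Arnt2, Yam1, Scube1, Sox5 and Prkg2, none of which passed edgeR's threshold over all genes.

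Among the panel genes, Prkg2, which encodes cGMP-dependent protein kinase 2, was lower in all 4 LAQ libraries than in any control library. It averaged 15.2 ± 1.57 CPM in control and 9.13 ± 2.82 CPM in LAQ (SD, n = 4 each), a log2 fold change of -0.74 ± 0.19 (SE). Its edgeR adjusted p was 0.228 over all genes and 0.0209 adjusted over the list alone, the list being the panel of 8 genes. Because the study itself reports Prkg2 for this treatment, the second value is not independent evidence. The adjusted p was 0.04996 with DESeq2 and 0.0197 with edgeR without LAQ 7, and it ranged from 0.00312 (cortical score as covariate) to 0.743 (thalamic and habenular score as covariate) over the alternatives and regional covariates. With the thalamic and habenular score, the log2 fold change of Prkg2 was -0.49 ± 0.24 (SE). Cyp1b1, a cytochrome P450 induced by the aryl hydrocarbon receptor, averaged 4.11 ± 1.56 CPM in control and 6.90 ± 0.70 CPM in LAQ. Its log2 fold change was 0.73 ± 0.24 (SE), with an edgeR adjusted p of 0.317 over all genes and 0.0432 adjusted over the list alone. The 0.0432 depends on Prkg2, which ranked ahead of Cyp1b1 in the panel and was chosen with the study in mind. It is therefore not independent evidence either. Ahr, the receptor gene, stood at a log2 fold change of -0.23 ± 0.15 (SE).

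Myrf, the transcription factor that drives myelin gene expression, averaged 97.3 ± 7.71 CPM in control and 107 ± 12.5 CPM in LAQ, a log2 fold change of 0.13 ± 0.09 (SE), or 0.06 without LAQ 7. Mbp (myelin basic protein) stood at 0.17 ± 0.09 (SE). Htt, counted as the mouse gene on chromosome 5, stood at -0.01 ± 0.10 (SE). No separate value of the mutant huntingtin fragment was examined, so this does not tell how the transgene responded. Ppargc1a, a coactivator of mitochondrial biogenesis, had a log2 fold change of -0.07 ± 0.10 (SE). Ppargc1a stood at -0.17 without LAQ 7, -0.04 without control 2 and -0.03 without LAQ 5 or LAQ 6. None of these 4 genes passed edgeR's test over all genes, with adjusted p of 0.521 (Mbp) to 0.979 (Htt), or adjusted over the list alone, with 0.230 to 0.901.

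The list of myelin proteins and mature oligodendrocyte markers rose relative to the other genes by camera with its preset correlation (adjusted p = 9.93e-09), a call lost at adjusted p = 0.501 with an estimated correlation. All 20 measured members had a positive log2 fold change, with a mean of 0.20, and 3 of them (Tspan2, Gjb1 and Opalin) passed adjusted over the list alone while 0 passed over all genes. Tspan2, a tetraspanin of the oligodendrocyte membrane, stood at 0.35 ± 0.08 (SE), and Gjb1, a gap junction protein, at 0.34 ± 0.09 (SE). Opalin, a glycoprotein of the myelin paranode, stood at 0.29 ± 0.09 (SE) and Cnp, a myelin phosphodiesterase, at 0.21 ± 0.07 (SE). The exact permutation p of the list was 0.0286, the smallest it can give, or 0.362 after adjustment. The mean score of the list was highest in LAQ 7 (1.45) and lowest in control 3 (-1.19). The list of oligodendrocyte transcription regulators was not called (camera adjusted p = 0.512), with a mean log2 fold change of -0.01, a median of 0.07 and an upward camera direction. Of its 11 members, Tcf7l2, which the thalamic list also holds, stood at -0.73 ± 0.23 (SE), and Sox10, a regulator of the whole lineage, at 0.17 ± 0.08 (SE). Oligodendrocyte precursor markers (camera adjusted p = 0.778), newly formed oligodendrocyte markers (0.636), cholesterol synthesis genes (0.537) and fatty acid and sphingolipid synthesis genes (0.176) were not called either.

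Ependymal markers rose by the same camera test (adjusted p = 6.04e-07), but not at adjusted p = 0.501 with an estimated correlation. All 11 members were higher, with a mean log2 fold change of 0.54, and 5 passed adjusted over the list alone. The ciliary genes Tmem212 (0.75 ± 0.20, SE), Foxj1 (0.64 ± 0.19), Dynlrb2 (0.91 ± 0.27) and Tekt1 (0.84 ± 0.27) had its smallest p-values. The choroid plexus list rose as well (adjusted p = 1.61e-05, but adjusted p = 0.619 with an estimated correlation), with 11 of 12 members higher, a mean of 0.63 and 0 members past adjusted over the list alone. That mean was 0.34 without control 2, 0.38 without LAQ 5 and 1.05 without control 4. Its scores ranged from -1.82 in control 2 to 1.09 in LAQ 5. The blood cell list rose (adjusted p = 7.07e-05, but adjusted p = 0.501 with an estimated correlation) with 5 of 5 members higher, among them the haemoglobin genes Hbb-bt (0.79 ± 0.22) and Hba-a1 (0.47 ± 0.20), whose near-identical copies make their counts uncertain.

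Markers of neighbouring neurons moved in different directions. The hippocampal and dorsal midline list rose (camera adjusted p = 5.27e-06, but adjusted p = 0.501 with an estimated correlation), with 10 of 10 members higher, a mean log2 fold change of 0.88, and 5 members past adjusted over the list alone. Tdo2, which encodes a tryptophan dioxygenase, stood at 1.79 ± 0.57 (SE), C1ql2 at 1.04 ± 0.37 and Prox1, a transcription factor of dentate granule cells, at 0.67 ± 0.24, or 0.38 without LAQ 5. The thalamic and habenular list fell (adjusted p = 1.52e-05, but adjusted p = 0.501 with an estimated correlation), with 9 of 10 members lower and a mean of -0.54, and Rora, a nuclear receptor, stood at -0.49 ± 0.13 (SE). The cortical excitatory list fell (adjusted p = 0.000277, but adjusted p = 0.501 with an estimated correlation), with 10 of 14 members lower, 4 of them past adjusted over the list alone. Its leading members were the upper-layer transcription factor Cux2 (-0.76 ± 0.15, SE) and Mef2c (-0.42 ± 0.10), both of which DESeq2 called. The cortical call was lost without LAQ 7 (adjusted p = 0.259), whose score was -1.32 against -0.58 to 0.55 in the other 7 libraries. The striatal list was not called (adjusted p = 0.636), with a mean of 0.08 and a downward camera direction, and its scores ran from -2.05 in LAQ 5 to 1.46 in LAQ 7.

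**Figure D2:**
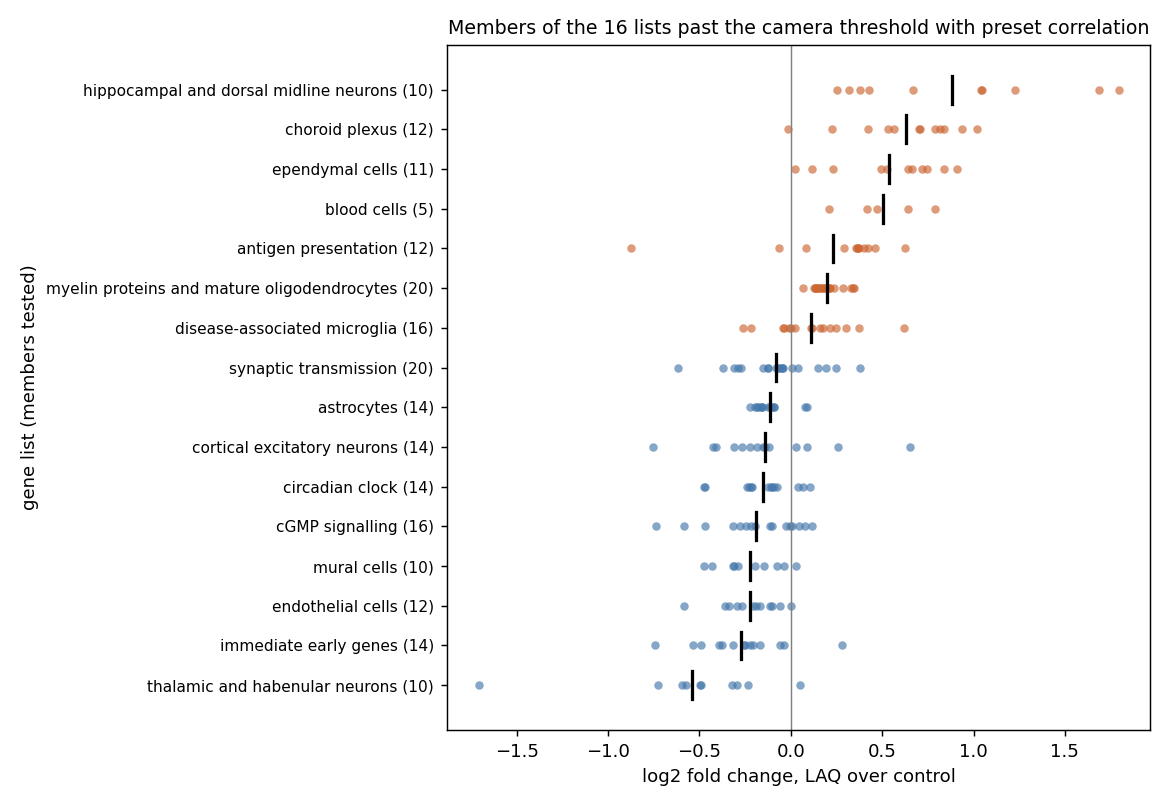
Log2 fold change (LAQ over control) of each tested member of the 16 lists past the camera threshold with its preset correlation, with 1 point per gene, lists called higher in orange and lower in blue, and the list mean as a black bar. The 20 myelin genes all lie above 0 around a mean of 0.20, while the means run from -0.54 (thalamic and habenular) to 0.88 (hippocampal), and 0 of the 16 calls held with an estimated correlation.

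Genes of synaptic transmission fell by camera (adjusted p = 0.0241, but adjusted p = 0.620 with an estimated correlation), with 14 of 20 members lower and a mean log2 fold change of -0.08. That mean was -0.02 without LAQ 7, -0.05 without control 3 and -0.00123 with the cortical score as covariate (adjusted p = 0.759). Stx1a, a syntaxin of synaptic vesicle fusion, averaged 225 ± 21.5 CPM in control and 147 ± 21.6 CPM in LAQ, a log2 fold change of -0.62 ± 0.11 (SE), and DESeq2 called it. Dlg4, which encodes the scaffold PSD-95, stood at -0.37 ± 0.09 (SE), and these 2 members passed adjusted over the list alone. Immediate early genes fell (adjusted p = 0.00363, but adjusted p = 0.620 with an estimated correlation), with 13 of 14 members lower, led by Arc at -0.54 ± 0.15 (SE) and Fosb at -0.75 ± 0.31, or -0.45 for Fosb without control 2. Circadian clock genes fell (adjusted p = 0.00957, but adjusted p = 0.620 with an estimated correlation), with 11 of 14 lower, led by Nr1d1 at -0.22 ± 0.07 and Per1 at -0.47 ± 0.17. The cGMP signalling list fell (adjusted p = 0.0196, but adjusted p = 0.501 with an estimated correlation), with 12 of 16 members lower and a mean of -0.19. Beside Prkg2, Gucy1a2, a guanylate cyclase subunit, stood at -0.47 ± 0.16 (SE), and Npr2, a natriuretic peptide receptor, at -0.20 ± 0.08. Since this list was drawn up around Prkg2, its direction is not independent evidence. The synaptic call was lost without LAQ 7 (adjusted p = 0.612) or control 3 (0.143), the immediate early call without control 2 (0.349) or LAQ 7 (0.0856), the clock call without LAQ 8 (0.242) and the cGMP call without LAQ 5 (0.0709).

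Astrocyte markers fell (camera adjusted p = 0.00662, but adjusted p = 0.619 with an estimated correlation), with 12 of 14 members lower and a mean of -0.12, led by Atp1b2, a sodium pump subunit, at -0.22 ± 0.07 (SE) and Slc1a2, a glutamate transporter, at -0.16 ± 0.07. Endothelial markers fell (adjusted p = 0.00642, but adjusted p = 0.620 with an estimated correlation), as did mural markers (adjusted p = 0.0480, but adjusted p = 0.692 with an estimated correlation), with 11 of 12 and 9 of 10 members lower, led by the transporter Abcb1a at -0.58 ± 0.24 and Vtn (vitronectin) at -0.31 ± 0.17. Without LAQ 6 they stood at -0.38 and -0.17, and Vtn stood at -0.20 without control 4. No member of these 3 lists passed adjusted over the list alone. Without LAQ 6 the endothelial (adjusted p = 0.321) and mural (0.659) calls were lost, and without LAQ 8 the astrocyte call (0.0795). Leaving out control 4 also ended the endothelial (0.0526) and mural (0.179) calls, and the mural call was lost without control 2 (0.0732), control 3 (0.0741) or LAQ 5 (0.0893).

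Of the immune lists, antigen presentation rose (camera adjusted p = 0.000633, but adjusted p = 0.619 with an estimated correlation), with 10 of 12 members higher and a mean log2 fold change of 0.23. The class I genes H2-K1 (0.62 ± 0.15, SE) and H2-D1 (0.46 ± 0.12) passed adjusted over the list alone and were called by DESeq2, although their paralogs make the counts uncertain. B2m, the class I light chain, stood at 0.36 ± 0.12 and Ciita, the class II transactivator, at -0.88 ± 0.37. Disease-associated microglia markers rose (adjusted p = 0.0337, but adjusted p = 0.620 with an estimated correlation), with 11 of 16 higher, led by Cd9 at 0.30 ± 0.09 and Lpl at 0.37 ± 0.14, or 0.19 for Lpl without LAQ 8. The call was lost without control 2 (adjusted p = 0.356), control 3 (0.0741) or LAQ 8 (0.283). The interferon list (camera adjusted p = 0.118), aryl hydrocarbon receptor targets (0.236), NF-kappa-B and cytokine genes (0.202) and homeostatic microglia (0.199) were not called. Most of the cytokine genes, among them Il1b, Tnf, Il6 and Ccl2, and the receptor targets Cyp1a1 and Cyp1a2 lay below the expression filter. A change in those genes was therefore not tested. Among the 6 receptor targets tested, Ahrr, a repressor of the receptor, stood at 1.22 ± 0.47 (SE) beside Cyp1b1. Of these 6, 4 were higher and 2 lower, with a median log2 fold change of 0.10, and 0 passed adjusted over this list alone.

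**Figure D3:**
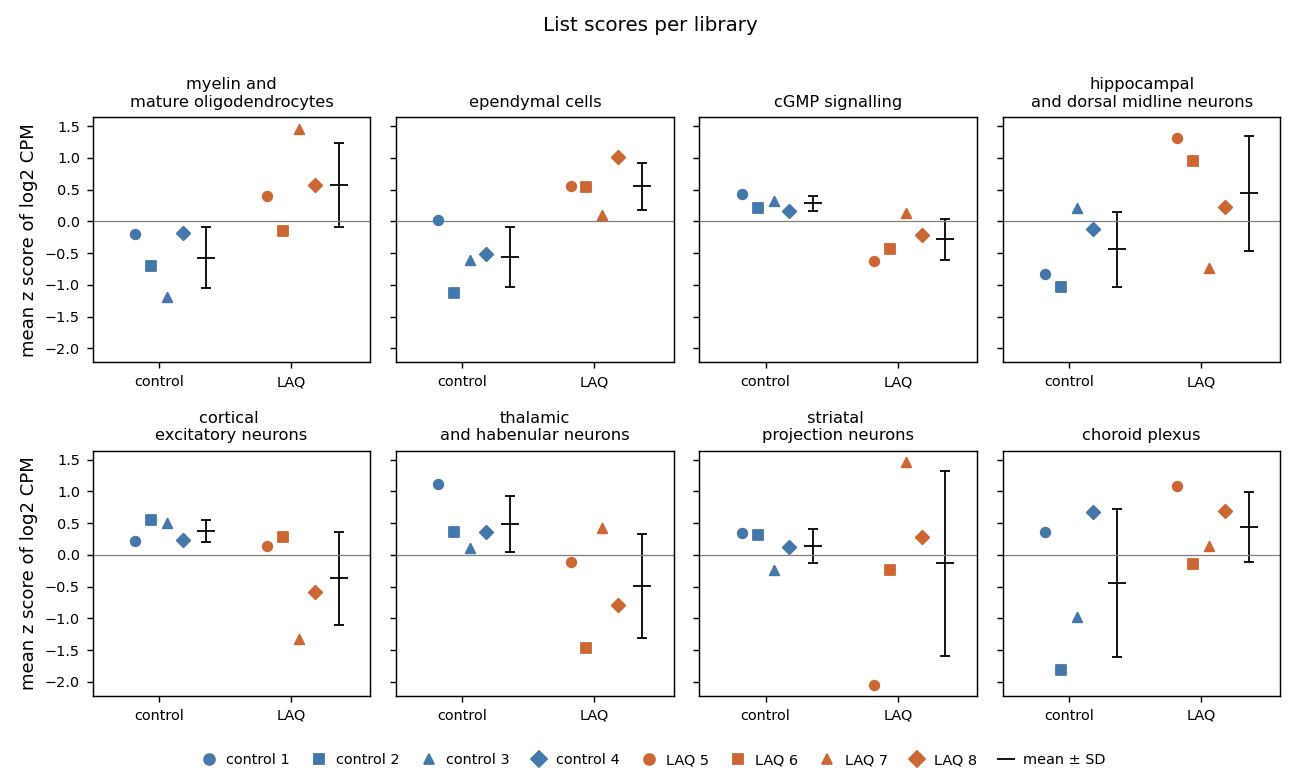
Mean z score of log2 CPM over the members of 8 gene lists in each library, with control libraries in blue, LAQ libraries in orange and the mean ± SD of each group in black. LAQ 7 had the highest myelin (1.45) and striatal (1.46) scores and the lowest cortical score (-1.32), LAQ 5 the lowest striatal score (-2.05), and the myelin, ependymal and cGMP scores separated the groups without overlap.

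In all, camera called 16 of 38 lists, 7 higher and 9 lower, and the other 22 had adjusted p of 0.118 to 0.778. With an estimated correlation and with fry's directional test 0 of the 38 lists passed, and the smallest adjusted p with an estimated correlation was 0.501. Fry's mixed test lets members move either way and gives a list no direction. It passed ependymal cells (adjusted p = 0.0178), synaptic transmission (0.0178), aryl hydrocarbon receptor targets (0.0274) and fatty acid and sphingolipid synthesis (0.0387). The exact permutation called 0, but its smallest possible p of 0.0286 could hardly pass after adjustment over 38 lists, so that count says little. Covariates ended further calls. With the cortical score these were the immediate early genes (adjusted p = 0.374), synaptic transmission (0.759), disease-associated microglia (0.139) and, by construction, the cortical list (0.907). With 1 surrogate variable they were endothelial cells (0.0606), the clock genes (0.0624), cGMP signalling (0.0811) and mural cells (0.359). All means and p-values rest on 4 libraries per group.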

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

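Of 72 sets of 4 libraries examined (the named genes in each group and similar values), 1 held a library far from its other 3, where chance gives about 3.6. Mbp stood at 6391 CPM in control 3, and the nearest of the other control libraries stood at 7414 CPM. The gap was 0.832 of the range of the group, just past the value used to single out a library. Control 3 also had the lowest myelin list score, -1.19. No explanation was tested for this value alone.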

How the results depend on the processing

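No paired analysis was possible because the replicate numbers of the control and LAQ libraries do not overlap. Direction was stable for the 16 called lists and 65 named genes, except as given here, while the number of calls was not. The estimated correlation, fry and the permutation reuse the list means of the main fit, and robust edgeR leaves the log2 fold changes as they were. Those settings could therefore not turn a direction. Of 256 list values under other settings, 179 kept their direction and side of the threshold, 76 were no longer past it, and 1 turned: the cortical excitatory list stood at 0.00476 with the cortical neuron score as a covariate, where that score is built from the same genes. Of 1300 gene values, 1197 were the same, 98 came past the threshold, and 5 turned, all of Htt, whose main value was -0.01: 6.35e-05 without a filter, 0.0245 with the cortical covariate, and -0.0974 to 0.0519 leaving out 1 library. The 0 higher and 0 lower genes of the main test became 27 and 102 with DESeq2, whose scaling and filter also differ (15403 genes adjusted), 5 and 20 without a filter (24 of these 25 shared with DESeq2), 3 and 22 with 1 surrogate variable, 334 and 423 with the cortical covariate, and 0 and 1 (BC030499) with voom and sample weights. They became 19 and 43 without LAQ 5 and 7, a fit chosen after seeing the data. Leaving out 1 library gave 0 to 117 higher and 0 to 222 lower genes, the highest counts without LAQ 7. The other scalings, the filter at 1 CPM, robust edgeR, voom and a threshold of 0.1 gave 0. Genes at an unadjusted p under 0.05 became 1527 higher and 1820 lower with the cortical covariate, and 541 to 1418 higher and 713 to 1714 lower leaving out 1 library. Of the 129 DESeq2 genes, 115 were also called with the cortical covariate and 92 without LAQ 7, all in the same direction. The 16 called lists became 0 with an estimated correlation, 0 with fry's directional test and 0 with exact permutation, where the small number of assignments made any call after adjustment improbable. By fry's mixed test the ependymal and synaptic lists among the 16 passed (adjusted p = 0.0178 each). Apart from the construction of the cortical score, the cause of these changes was not tested. With 4 libraries per group, 40% of simulated 1.5-fold changes were recovered, so changes of that size could go undetected. The simulated genes varied independently, without shared differences between libraries such as those of LAQ 7, so recovery in the real libraries may differ.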

Other observations

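The genes of this paragraph and the next were chosen after their values had been seen. Rims1, a scaffold of the presynaptic active zone, averaged 202 ± 8.27 CPM in control and 146 ± 16.4 CPM in LAQ (SD, n = 4 each), a log2 fold change of -0.47. Its relatives Rims3 and Rims4 stood at -0.79 and -0.53, and Rims2 at -0.20. DESeq2 called Rims1 (adjusted p = 0.000682), Rims3 (0.000523) and Rims4 (0.000653), while edgeR's adjusted p was 0.136 for Rims1, 0.140 for Rims3, 0.136 for Rims4 and 0.462 for Rims2.

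Hes5, a target of Notch signalling in glial progenitors, averaged 22.6 ± 3.06 CPM in control and 14.2 ± 2.65 CPM in LAQ, a log2 fold change of -0.67. Col5a1, a fibrillar collagen, stood at -0.82, Hopx, a homeodomain cofactor, at 0.58, and Tmeff2, a transmembrane protein, at 0.31. All 4 were called by DESeq2, with adjusted p of 0.0161 for Hes5, 0.000682 for Col5a1, 0.0145 for Hopx and 0.00424 for Tmeff2, and none by edgeR (0.140 to 0.181).

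The tests of the 3 patterns below were partly chosen after the results had been seen: those with control 3 and LAQ 7 exchanged, that with an estimated correlation, those with the regulator list and with the myelin and cortical scores, and the covariates other than cortex for the number of genes. The verdicts on Prkg2, swapped labels and white matter were made stricter after their values were known.

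Miat, Arnt2, Yam1, Scube1 and Dgat2 had the smallest p of 1750 genes at an unadjusted edgeR p under 0.05, and 3 of the 35 splits of the libraries gave as many, the labelled one included (highest other 2818), as did 2 of 35 for the 129 DESeq2 calls (highest other 713), so chance was not excluded, although those other splits differ from the labelled one by exchanging LAQ 7 with 1 control library. A loess correction on GC content left 9.88% of genes at that p (733 higher, 747 lower). The correction on transcript length left 11.3% (897 higher, 796 lower), so neither removed the excess. Before any correction, GC content separated the groups, with a rank correlation per library of -0.0961 to -0.0564 in LAQ and -0.0176 to 0.176 in control. The GC correction lowered the share from 11.2% on the same genes to 9.88%, so a GC bias in part of these genes stays open. The cortical score as covariate raised the share to 21.2%. That score was lowest in LAQ 7 (-1.32), and 319 of the 339 genes called without LAQ 7 were also called with it. It could therefore not tell an uneven share of cortex from that library. The hippocampal and thalamic scores lowered the 1750 genes to 1245 and 1088, which leaves uneven dissection of those regions open. The split that exchanged control 3 and LAQ 7 gave the 2818 and 713 genes and 233 edgeR calls, which points to a structure of the samples. Over 474 genes called in the other 6 libraries, LAQ 7 lay at 0.099 (quartiles -0.349 to 0.467) between the control (0) and LAQ (1) means. Control 3 lay at 0.458 (quartiles 0.257 to 0.681). Its median was below the bound of 0.5 set beforehand as counting against swapped labels, but its quartiles lay on both sides. Control 3 was nearer to the other controls (chi-square per degree of freedom 4.66 to 6.07) than to any LAQ library (6.76 or more), which speaks against swapped labels. LAQ 7 was nearer to every control (9.92 to 14.0) than to any LAQ library (16.1 to 25.6). It was also farther from each control than any 2 controls were from each other (4.24 to 6.07), so it stood apart from both groups. A swap was thus not shown, but it stays open. With the hippocampal score as covariate the exchanged split gave 0 calls, so hippocampal tissue in the pieces may explain it, although that score itself separates the exchanged groups and the labelled split also gave 0.

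Prkg2 was lower in each LAQ library than in any control library, and its log2 fold change of -0.74 became -0.75 after the GC correction. Of 6 regional scores used as covariate, the thalamic and habenular one brought it nearest to 0, at -0.49 ± 0.24 (SE), with an edgeR p of 0.0669. The ratio of -2.02 met the bound of 2 set beforehand by 0.02 only, which was not taken as deciding. The hippocampal score gave -0.51 ± 0.18 (SE), and the striatal, septal, cortical and myelin scores gave -0.70 to -1.29. Within groups Prkg2 followed the cortical (r = -0.94), septal (0.94) and striatal (0.93) scores more closely than the thalamic one (0.46). The thalamic and hippocampal lists also differed between the groups (mean log2 fold changes of -0.54 and 0.88), so these covariates cannot separate tissue from treatment. Thalamic or hippocampal tissue in the pieces may account for part of the difference. DESeq2 called Prkg2 (adjusted p = 0.04996), but the gene was examined because the study reports it, which limits what that value adds.

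Tspan2, Gjb1, Opalin and Cnp led the myelin list, 1 of the 16 lists called, but 7 of 35 splits called as many lists, the labelled one included (highest other 19), and 0 of 16 held with an estimated correlation, so members that vary together between libraries could give such calls. Its log2 fold change exceeded that of the regulators by 0.14 ± 0.06 (SE) without Tcf7l2 (exact permutation p = 0.0571), which does not exclude more white matter in the LAQ pieces. Within groups the myelin score fell as the cortical score rose (Pearson r = -0.87, Spearman rho = -0.95, 8 libraries). The permutation p was 0.00347 for each, and this was the 1 pair of lists so tested. Without LAQ 6 and 7 the Pearson r was -0.70. With the cortical score as covariate the myelin list mean was 0.12 and its preset camera call was kept (adjusted p = 0.00370). The share of cortex could therefore explain part of the rise. The kept call cannot show whether that share explains the whole, because the preset correlation lies below the 0.44 estimated for this list. Without LAQ 7 the mean was 0.15 against 0.20, the preset camera call was kept (adjusted p = 0.000245), and LAQ 5, 6 and 8 each lay above every control (mean log2 CPM 7.38 or more against 7.37 or less), so the rise was not seen in LAQ 7 alone, and how much of it that library carries stays open. Treatment as the cause of the rise therefore stays open beside the make-up of the pieces.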
